A study of Homo sapiens with 6 samples.

How the data were processed

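RNA was taken from LoVo and LoVo-HM cells with Trizol and made into libraries with an Illumina TruSeq RNA kit, per the labels' protocols, with 3 libraries per group and 6 in all. The authors deposited 1 table of FPKM values with a column for each library. The genome build was GRCh38, per the submitters' processing notes. The aligner, the counter, the annotation release, the strand setting and the read depth are not given in the sources used here. The deposited FPKM table holds 24580 rows. Of these, 19974 carry an Ensembl identifier and a symbol, and all 19974 identifiers matched GENCODE 29, 19922 as protein-coding genes and 52 as other types, so that positions could be taken from it. The other 4606 rows are gene models without a symbol, which hold 1.4 to 1.67% of the FPKM of a library. They stayed in the fit (1882 tested, 657 past the threshold) and no such row is named. The table has 17 symbols used by 2 rows each and 3626 rows at 0 in every library. No column was identical to another, and every column belonged to a library of this series.

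FPKM values are not counts, so no count model was used. Values below 0.3 FPKM were checked for steps worth 1 read, which would give the relative depth of the libraries. Over 954 genes the commonest bin of 0.05 log2 units held 3.67% of the ratios, so no steps were found and the depth remains unknown.

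Values were used as deposited, without further scaling, as log2(FPKM + 1). Genes with a mean of at least 0.5 FPKM over the 6 libraries were tested, 14487 in all. LoVo-HM was compared with LoVo by limma 3.58.1 in R 4.3.3, with an intensity trend in the variance and two-sided moderated tests, and Benjamini-Hochberg adjusted p-values under 0.05 were called. A change of at least 2-fold means an absolute log2 difference of at least 1 on this scale. Lists of genes with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 31 lists. Camera was repeated with a correlation estimated for each list, and limma's fry was run as a test of each list by itself. The repeat of camera also takes its p-values from the residual degrees of freedom of the 6 libraries, so they reflect more than correlation. Of 37 fixed lists, 6 had too few tested members (secretory lineage, fibroblast, immune, endothelial, hepatocyte and lung epithelial markers). Chromosomes 1 to 22 and X were tested as sets in the same way.

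The test, the samples in each fit, the lists, the rule for naming genes and most of the alternatives were set before the data were examined. The rule names the 12 largest increases and the 12 largest decreases among genes with an adjusted p under 0.05, no overlap between the groups, at least 5 FPKM in the higher group and a real gene symbol. Sex-linked marker genes were left out of it. It also names up to 4 members of each list, those with the smallest p, and 15 genes whatever their result: CDH1, EPCAM, VIM, ZEB1, CDX2, KRT20, CEACAM5, LGR5, AXIN2, MYC, MKI67, MET, MACC1, S100A4 and CD44. It would name up to 3 members of a chromosome called as shifted, and none was called. Genes outside the rule are said to be named after their values were seen, except NME1 and NME2, which are given beside their readthrough.

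The fit was tested on simulated data with 14487 genes, the spread of these libraries and 200 changed genes. It recovered 24% of changes of 0.25 log2 units, 96% at 0.5, 98% at 1 and 100% at 2, with 5.36% false calls, and called 0 genes where none was changed. The changed genes were all drawn from above about 2 FPKM, so recovery among lower tested genes was not measured. Camera called a simulated list shifted by 0.3 log2 units (adjusted p = 7.55e-40) and 0 of 200 random lists. The simulated genes varied independently, whereas the estimated correlation reached 0.62 in a real list (cytosolic ribosomal proteins). The simulation therefore does not show how often camera falsely calls lists of correlated genes.

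Alternatives were pseudocounts of 0.1 and 0.5, no filter and a filter at a mean of 2 FPKM, rescaling each library to the same total, median-ratio scaling, quantile normalization, variance fits without a trend and with robust estimates, the replicate number as a block, and leaving out each library in turn. Chosen after the data were seen were a fit without the models lacking a symbol, a fit without mitochondrially encoded genes, and camera on ranks. Rescaling set each library to a total of 1e+06, and the fit without mitochondrially encoded genes was rescaled too. The closing section gives the effect of all these alternatives.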

Results

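Messenger RNA levels were measured by RNA sequencing in LoVo, an established human colorectal adenocarcinoma cell line, and in LoVo-HM, taken here as a subline of LoVo and described in the labels as highly metastatic. Each of the 2 groups had 3 libraries, so the table held 6 libraries in all, and the labels record no treatment. Expression was deposited as FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of each library), with library totals of 434108 to 439082 FPKM in LoVo and 424624 to 428265 FPKM in LoVo-HM. Read counts and depth are unknown, so no counting intervals or detection limits are given. Pearson correlations of log2(FPKM + 1) were 0.991 to 0.993 between libraries of 1 group and 0.936 to 0.938 between libraries of different groups. Levels below are mean FPKM ± SD with n = 3 libraries per group, and log2 differences are LoVo-HM minus LoVo ± SE on the log2(FPKM + 1) scale, which understates the change of genes with low values. Adjusted p-values are from limma with Benjamini-Hochberg adjustment over 14487 genes, and positions are GRCh38.

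The comparison of LoVo-HM with LoVo asks which transcripts differ between the lines. The labels do not say how LoVo-HM was derived from LoVo, and neither line was checked against a reference profile of LoVo. All 21 tested antigen presentation genes, which include those of MHC class II for presenting peptides to helper T cells, fell in LoVo-HM (camera adjusted p = 1.45e-18, adjusted p = 0.0306 with an estimated correlation). Of 23 epithelial junction and polarity genes 15 fell (camera adjusted p = 0.000293, adjusted p = 0.0721 with an estimated correlation). In the NF-kB list of cytokines, chemokines and pathway genes, 17 of 18 tested members fell (camera adjusted p = 2.01e-11, adjusted p = 0.0306 with an estimated correlation). KRT17, COL3A1, WNT5A and VIM rose. CD74, the class II invariant chain (ENSG00000019582, chromosome 5, 150401637 to 150412929), fell from 606 ± 18.9 to 7.62 ± 0.268 FPKM (log2 difference -6.14 ± 0.046, limma adjusted p = 3.15e-11). CDH1, which encodes the adherens junction protein E-cadherin (ENSG00000039068, chromosome 16, 68737225 to 68835548), fell from 48.0 ± 1.38 to 7.91 ± 0.359 FPKM (-2.46 ± 0.055, limma adjusted p = 5.9e-09). WNT5A, a ligand of non-canonical Wnt signalling (ENSG00000114251, chromosome 3, 55465715 to 55490539), rose from 1.34 ± 0.261 to 44.2 ± 0.271 FPKM (4.28 ± 0.084, limma adjusted p = 2.91e-09). In all, 6508 of the 14487 tested genes (44.9%) passed the threshold of 0.05, 3161 higher and 3347 lower in LoVo-HM. Of these, 950 changed at least 2-fold, 344 higher and 606 lower, and with a pseudocount of 0.1 in place of 1 the count was 1528, 548 higher and 980 lower. At least 8-fold changes were seen in 35 higher and 61 lower genes. The values of the groups did not overlap for 55% of the tested genes, where chance gives 10%.

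Among the 12 named genes with the largest increases, 5 were type I keratins of the chromosome 17 cluster, which encode filament proteins of epithelia and hair. KRT17 (chromosome 17, 41619441 to 41624842) rose from 1.12 ± 0.310 to 59.7 ± 3.71 FPKM (4.85 ± 0.107, limma adjusted p = 5.48e-09). KRT13 rose from 0.126 ± 0.0248 to 29.7 ± 1.54 FPKM, and the hair keratins KRT36 and KRT34 from 0.0178 ± 0.0154 to 27.9 ± 1.40 and from 0.0187 ± 0.0325 to 20.7 ± 0.317 FPKM. KRT31 stood at 16.5 ± 1.28 FPKM in LoVo-HM and was listed at 0 in all 3 LoVo libraries. Keratins have close paralogs, so the value of each is uncertain, but the summed level of the chromosome 17 keratins other than KRT19 was 189 ± 0.749 FPKM in LoVo-HM and 8.77 ± 0.825 FPKM in LoVo. LRRN3, a leucine-rich repeat neuronal protein (chromosome 7, 111091006 to 111125454), had the largest increase with a pseudocount of 1, from 0.0180 ± 0.0197 to 32.3 ± 1.82 FPKM (5.03 ± 0.075, limma adjusted p = 7.15e-10). With a pseudocount of 0.1 the log2 difference of NME1-NME2 was larger than that of LRRN3. COL3A1, the fibrillar collagen III chain, rose from 0.625 ± 0.102 to 38.3 ± 2.38 FPKM (4.60 ± 0.079), and ALPK2, an alpha-kinase, from 0.0539 ± 0.0341 to 22.4 ± 0.685 FPKM. ARHGAP28, a GTPase-activating protein, and CSN3, the milk protein kappa-casein, were at 18.6 ± 1.48 and 17.6 ± 2.77 FPKM in LoVo-HM and listed at 0 in every LoVo library. The readthrough NME1-NME2 was at 28.5 ± 3.34 FPKM in LoVo-HM and listed at 0 in LoVo, an uncertain value because it shares its reads with NME1 (181 ± 6.86 against 157 ± 7.08 FPKM) and NME2.

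The 12 named genes with the largest decreases held 5 of the class II pathway. HLA-DRA, the class II alpha chain (ENSG00000204287, chromosome 6, 32439842 to 32445046), had the largest decrease, from 395 ± 10.7 to 0.268 ± 0.122 FPKM (-8.29 ± 0.075, limma adjusted p = 8.76e-11). HLA-DRB1 fell from 123 ± 5.61 to 0.240 ± 0.149 FPKM, HLA-DPA1 from 173 ± 0.452 to 1.03 ± 0.254 and HLA-DPB1 from 62.1 ± 0.25 to 0.430 ± 0.133. HLA genes share reads with close paralogs and are read against reference alleles, so the split between them is uncertain, whereas CD74 is a gene without a close copy. KRT6A, a keratin of stratified epithelia, fell from 151 ± 3.83 to 0.839 ± 0.589 FPKM (-6.41 ± 0.185, limma adjusted p = 2.47e-08). TP63, a transcription factor of basal epithelial cells (chromosome 3, 189631416 to 189897279), fell from 36.1 ± 1.71 to 0.296 ± 0.0605 FPKM (-4.84 ± 0.074, limma adjusted p = 8.23e-10). PTHLH, the parathyroid hormone-related hormone, fell from 206 ± 6.78 to 2.13 ± 0.277 FPKM (-6.05 ± 0.072), and the neurotrophin receptor NTRK2 from 58.2 ± 2.88 to 0.735 ± 0.0991 (-5.09 ± 0.071). ALDH1A1, an aldehyde dehydrogenase that makes retinoic acid, fell from 245 ± 1.92 to 3.48 ± 0.765 FPKM (-5.79 ± 0.112). The ion transport regulator FXYD3 fell from 81.8 ± 3.72 to 0.725 ± 0.122 FPKM, and ANXA8, an annexin that shares reads with a near-identical copy, from 84.0 ± 3.36 to 1.65 ± 0.0963.

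**Figure D1:**
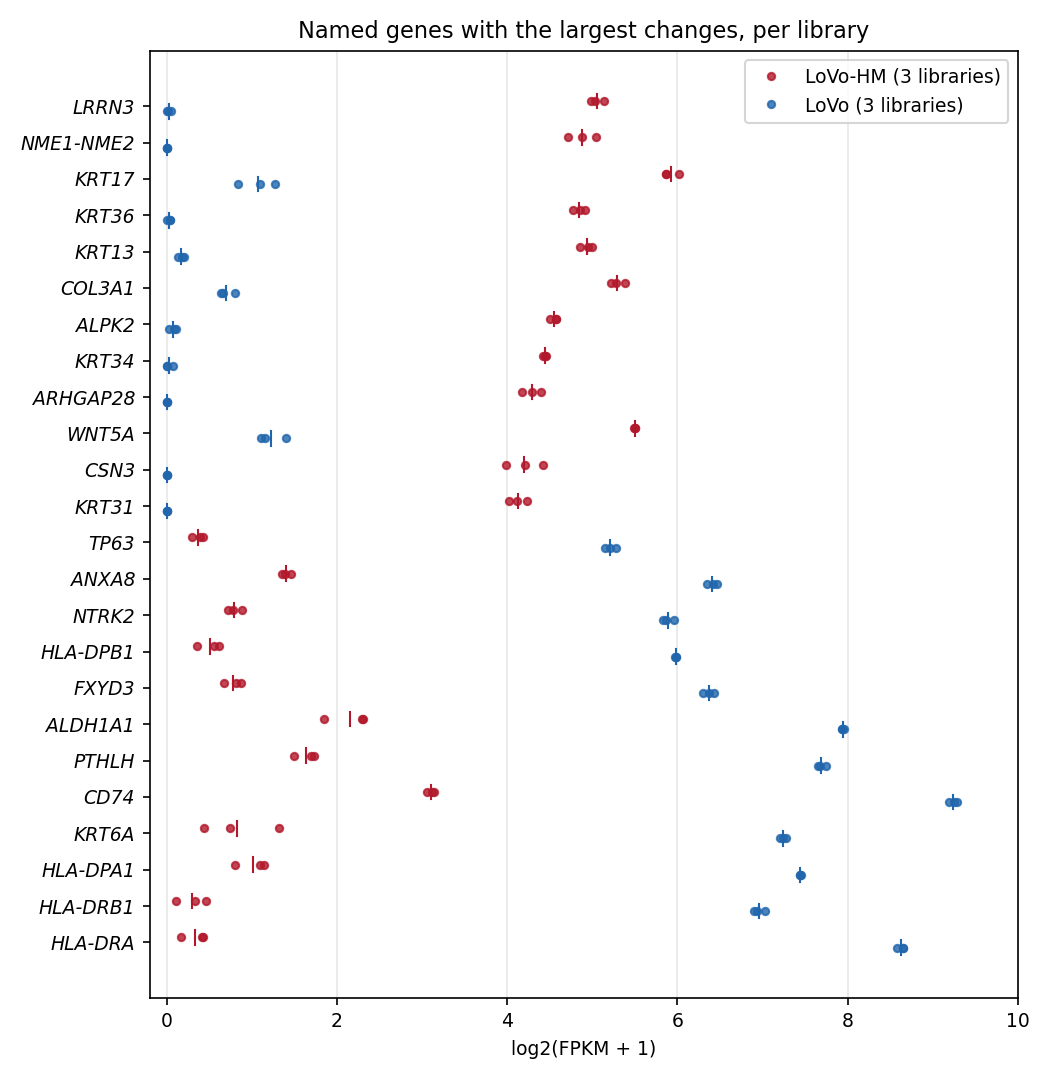
Expression of the 24 named genes with the largest changes, 1 row per gene, on a log2(FPKM + 1) axis, where each point is 1 library and each short line the mean of the 3 libraries of LoVo-HM (red) or LoVo (blue). The groups do not overlap for any of these genes, from HLA-DRA, at 395 FPKM in LoVo and 0.268 in LoVo-HM, to LRRN3, at 0.0180 FPKM in LoVo and 32.3 in LoVo-HM.

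Genes were also grouped in lists fixed before the values were seen, each tested by limma's camera against all other genes. Counts of list members refer to limma's threshold over all genes, and the counts adjusted over the list alone were the same except where given. All 21 tested members of the antigen presentation list fell in LoVo-HM, and all 21 fell adjusted over the list alone. The list had a median log2 difference of -1.49 (camera adjusted p = 1.45e-18, adjusted p = 0.0306 with an estimated correlation). Besides the class II genes above, 3 members were named after their values were seen. CIITA, the master activator of class II transcription, fell from 11.3 ± 0.445 to 0.343 ± 0.0274 FPKM (-3.2 ± 0.078). The class I heavy chain gene HLA-B fell from 511 ± 9.14 to 89.5 ± 2.15 FPKM (-2.5 ± 0.037), and B2M, the class I light chain, from 29.8 ± 3.84 to 18.3 ± 2.11 (-0.68 ± 0.107, limma adjusted p = 0.00106). In the major histocompatibility region (tested genes from 28903002 to 33789136 on chromosome 6), the 100 other tested genes had a median log2 difference of 0.13, 37 of them higher and 13 lower.

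**Figure D2:**
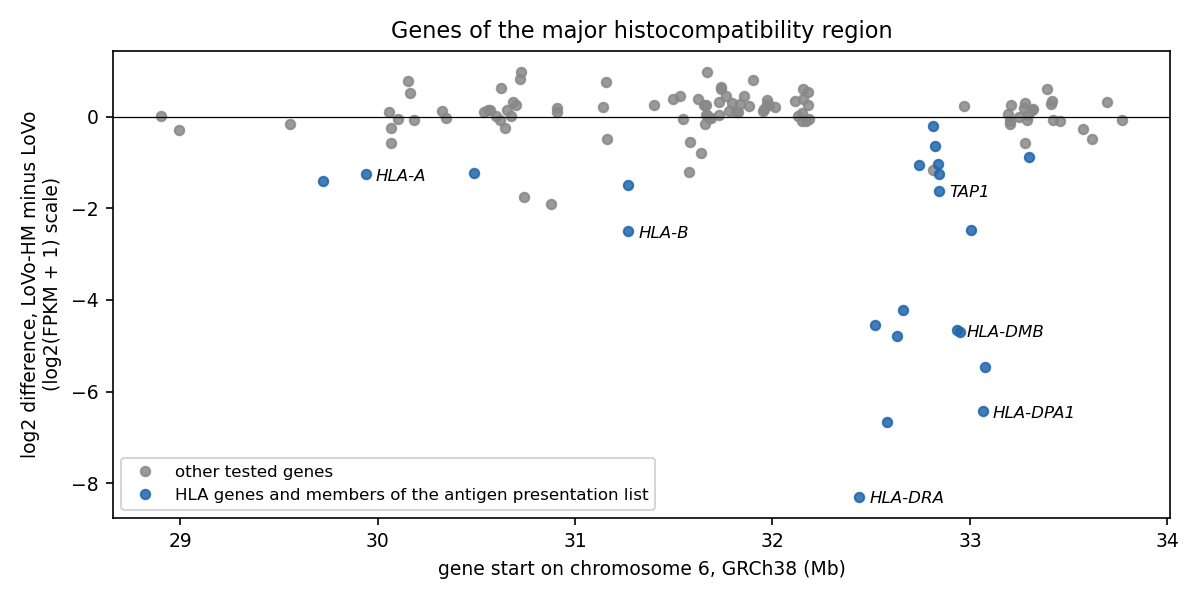
Log2 difference (LoVo-HM minus LoVo, log2(FPKM + 1) scale) of each tested gene in the major histocompatibility region against its start on chromosome 6 in megabases, with 1 point per gene. The 22 HLA genes and antigen presentation members (blue) have a median of -2.05, and 21 of them fell, while the 100 other genes (grey) have a median of 0.13.

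The NF-kB list of cytokines, chemokines and pathway genes had 28 members, of which 18 were tested and the others were too low. Of the 18 tested members, 17 fell and 1 rose. Their median was -1.5 (camera adjusted p = 2.01e-11, adjusted p = 0.0306 with an estimated correlation). The neutrophil chemokines CXCL8 and CXCL1 fell from 13.9 ± 0.255 to 0.451 ± 0.0858 FPKM (-3.36 ± 0.080) and from 53.3 ± 2.20 to 3.09 ± 0.857 FPKM (-3.75 ± 0.129). The pathway's feedback inhibitors fell too, TNFAIP3 from 17.9 ± 0.257 to 2.11 ± 0.217 FPKM and NFKBIA from 75.3 ± 1.48 to 21.1 ± 1.45. The member that rose was the monocyte chemokine CCL2 (1.19), named after its value was seen. Type I interferon response genes were lower on balance, with 13 of 27 lower, 4 higher and 10 not past the threshold (14 lower and 4 higher adjusted over the list alone). Their median was -0.23 (camera adjusted p = 0.0375, adjusted p = 0.386 with an estimated correlation). OAS1 and IFI44 fell (-2.26 ± 0.129 and -1.94 ± 0.106), whereas the membrane proteins IFITM3 and IFITM2, which are close paralogs, rose from 196 ± 5.31 to 394 ± 15.6 FPKM and from 35.6 ± 4.22 to 101 ± 7.06 FPKM. The interferon call was lost without LoVo replicate 3 (camera adjusted p = 0.0649) and without LoVo-HM replicate 1 (0.0503), and also with a minimum mean of 2 FPKM (0.0866) and without mitochondrially encoded genes (0.0502).

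Epithelial junction and polarity genes fell as a list, with 15 of 23 lower, 4 higher and 4 not past the threshold. Their median was -0.93 (camera adjusted p = 0.000293, adjusted p = 0.0721 with an estimated correlation). Besides CDH1, the desmosomal proteins JUP and DSP fell from 77.5 ± 1.2 to 19.8 ± 0.522 FPKM (-1.92 ± 0.045) and from 71.2 ± 2.41 to 19.4 ± 0.434 FPKM (-1.83 ± 0.048). EPCAM, an epithelial adhesion molecule, fell from 128 ± 1.99 to 51.7 ± 2.60 FPKM (-1.29 ± 0.048, limma adjusted p = 1.16e-07). KRT19, a simple-epithelial keratin, rose from 105 ± 6.81 to 389 ± 11.4 FPKM (1.88 ± 0.052). The mesenchymal and EMT list was higher, with 7 of 14 tested members higher, 3 lower and 4 not past the threshold (8 higher and 3 lower adjusted over the list alone). Its median was 0.38 (camera adjusted p = 0.0159, adjusted p = 0.164 with an estimated correlation). VIM, which encodes the intermediate filament vimentin, rose from 0.478 ± 0.122 to 14.0 ± 0.298 FPKM (3.35 ± 0.087, limma adjusted p = 1.38e-08), and ZEB1, a repressor of E-cadherin, from 0.278 ± 0.202 to 7.28 ± 0.384 (2.71 ± 0.121, limma adjusted p = 4.15e-07). TGFBI and FN1, which encode matrix proteins, rose from 0.852 ± 0.175 to 5.11 ± 0.0411 FPKM and from 1.06 ± 0.0843 to 4.19 ± 0.110. Members too low to test, named after their values were seen, went both ways. Mean FPKM in LoVo and LoVo-HM was 0.006 and 0.075 for N-cadherin (CDH2), 0.015 and 0.239 for SPARC, 0.022 and 0.549 for TNC, 0.005 and 0.025 for MMP2 and 0 and 0.047 for THY1. It was 0.394 and 0.164 for AXL, 0.476 and 0.323 for FOXC2 and 0.006 and 0 for ZEB2. TWIST1 and TWIST2 were listed at 0 in all 6 libraries.

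Integrins and laminins, which anchor epithelia to the basement membrane, fell in 14 of 19 tested genes, rose in 3 and did not pass the threshold in 2. Their median was -0.58 (camera adjusted p = 0.000123, adjusted p = 0.0721 with an estimated correlation). LAMB3 fell from 42.3 ± 1.28 to 6.39 ± 0.246 FPKM (-2.55 ± 0.056), the hemidesmosomal collagen COL17A1 from 13.8 ± 0.295 to 0.438 ± 0.0530 (-3.36 ± 0.076) and ITGA3 from 28.3 ± 1.09 to 6.48 ± 0.538 (-1.97 ± 0.069), while the collagen receptor chain ITGA1 rose from 0.362 ± 0.0270 to 6.20 ± 0.281 FPKM (2.40 ± 0.085). Growth factor receptors and ligands fell in 17 of 24 tested genes, rose in 4 and did not pass in 3. Their median was -0.45 (camera adjusted p = 0.00109, adjusted p = 0.0738 with an estimated correlation). EGFR fell from 21.9 ± 0.0161 to 7.46 ± 0.390 FPKM (-1.44 ± 0.059), EPHA1 from 25.9 ± 0.862 to 8.97 ± 0.513, the EGFR ligand TGFA from 11.8 ± 0.504 to 4.15 ± 0.169, and MET, the receptor of hepatocyte growth factor, from 93.0 ± 1.44 to 51.2 ± 1.18 FPKM (-0.85 ± 0.041, limma adjusted p = 6.95e-07). The list of matrix proteases and inhibitors was not called (camera adjusted p = 0.0943), with 5 of 19 higher, 10 lower and 4 not past the threshold. Its members KLK10 (-3.49 ± 0.064), SERPINB5 (-3.08 ± 0.069) and the collagenase MMP1 (-1.73 ± 0.101) fell, and the sheddase ADAM10 rose (1.36 ± 0.061).

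Genes reported in association with metastasis went both ways, with 6 of 23 higher, 11 lower and 6 not past the threshold (7 higher and 12 lower adjusted over the list alone). The list was not called (median -0.23, camera adjusted p = 0.25). It mixes genes reported to promote metastasis with reported suppressors such as NME1. A test of a shared direction therefore cannot decide whether either kind changed. MACC1, a transcriptional activator of MET, fell from 5.59 ± 0.121 to 0.108 ± 0.0325 FPKM (-2.57 ± 0.087, limma adjusted p = 6.82e-08). The hyaluronan receptor CD44 rose from 46.4 ± 2.24 to 106 ± 11.7 FPKM (1.17 ± 0.077, limma adjusted p = 4.93e-06), and ANXA2 from 273 ± 13.3 to 497 ± 25.6 (0.86 ± 0.051). S100A4 did not pass the test, at 56.0 ± 3.80 FPKM in LoVo and 59.7 ± 3.03 FPKM in LoVo-HM (0.09 ± 0.061, limma adjusted p = 0.26).

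Wnt/beta-catenin targets were higher on balance, with 7 of 17 higher, 4 lower and 6 not past the threshold. Their median was 0.2 (camera adjusted p = 0.0362, adjusted p = 0.24 with an estimated correlation). AXIN2, a feedback inhibitor of the pathway, rose from 35.8 ± 1.52 to 130 ± 5.87 FPKM (1.83 ± 0.052, limma adjusted p = 2.16e-08). SOX9, an intestinal stem and Paneth cell factor, rose from 1.57 ± 0.0946 to 29.2 ± 0.468 FPKM (3.56 ± 0.064), and APCDD1 from 1.03 ± 0.178 to 26.0 ± 1.13 (3.73 ± 0.083). RNF43, which removes Wnt receptors from the cell surface, fell from 17.3 ± 0.443 to 1.30 ± 0.231 FPKM (-3 ± 0.089). MYC did not pass the test, at 138 ± 2.37 FPKM in LoVo and 137 ± 2.03 FPKM in LoVo-HM (-0.02 ± 0.037, limma adjusted p = 0.741), and LGR5 was too low to test, at most 0.234 FPKM in any library. The Wnt call was lost without LoVo-HM replicate 2 (camera adjusted p = 0.0588) and in 5 other settings given in the closing section. In 1 of these, without a filter on low values, the median turned to -0.002 (camera adjusted p = 0.239).

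Stem cell markers were not called as a list (6 higher, 7 lower and 2 not past of 15, camera adjusted p = 0.512). Besides ALDH1A1, the pluripotency factor SOX2 fell from 32.7 ± 0.0556 to 4.47 ± 0.0833 FPKM (-2.62 ± 0.054) and ANXA1 from 289 ± 10.4 to 64.4 ± 5.61 FPKM (-2.15 ± 0.064). Of 25 colonocyte differentiation markers 6 were tested, of which 2 rose and 4 fell (camera adjusted p = 0.378). The intestinal transcription factor CDX2 rose from 8.39 ± 0.129 to 14.7 ± 0.960 FPKM (0.74 ± 0.065, limma adjusted p = 3.13e-05), and KRT20 was at 2.92 ± 0.475 FPKM in LoVo-HM and listed at 0 in LoVo. CA2, a carbonic anhydrase, fell from 28.3 ± 1.06 to 9.68 ± 0.618 FPKM, and HNF4A, a nuclear receptor of intestinal and liver cells, from 3.15 ± 0.326 to 0.340 ± 0.206. CEACAM5 was too low to test, at most 0.0560 FPKM in any library. Secretory lineage markers had 3 tested members, of which SCG2 (from 0.0429 ± 0.0559 to 12.8 ± 0.664 FPKM) and SYP (0.48 ± 0.109) rose and AGR2 fell (-2.46 ± 0.117).

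The mitotic cell cycle list rose, with 23 of 25 members higher and 2 not past the threshold. Its median was 0.36 (camera adjusted p = 3.07e-09, adjusted p = 0.0738 with an estimated correlation). CDKN3 rose from 103 ± 4.99 to 193 ± 6.26 FPKM (0.90 ± 0.048), the kinetochore protein CENPF from 30.7 ± 1.42 to 50.9 ± 2.07 (0.71 ± 0.054), and the proliferation marker MKI67 from 49.9 ± 1.55 to 64.4 ± 1.02 (0.36 ± 0.044, limma adjusted p = 0.000215). DNA replication genes rose in 22 of 26 and did not pass in 4 (24 higher adjusted over the list alone). Their median was 0.39 (camera adjusted p = 3.07e-09, adjusted p = 0.0721 with an estimated correlation). UHRF1, which guides maintenance DNA methylation, rose from 33.6 ± 0.759 to 68.9 ± 4.52 FPKM (1.01 ± 0.056), and the helicase subunits MCM5 and MCM7 by 0.72 ± 0.053 and 0.58 ± 0.041. Replication-dependent histones were not called (2 higher, 1 lower and 5 not past of 8, camera adjusted p = 0.92), with HIST1H2BK lower (-0.63 ± 0.047) and HIST1H2AC higher (0.51 ± 0.078).

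Mitochondrially encoded genes fell in 11 of 13 and did not pass in 2. Their median was -0.27 (camera adjusted p = 5.63e-05, adjusted p = 0.24 with an estimated correlation). With quantile normalization it was -0.057 and the call was lost (camera adjusted p = 0.0607). The complex I subunit genes MT-ND4 and MT-ND6 fell from 8739 ± 158 to 6157 ± 257 FPKM (-0.51 ± 0.039) and from 2864 ± 148 to 1901 ± 35.7 FPKM (-0.59 ± 0.043). Mitochondrially encoded genes made up 21.4 ± 0.480% of FPKM in LoVo and 18.1 ± 0.560% in LoVo-HM (two-sided exact permutation test, p = 0.1, the smallest p that 3 against 3 libraries can give). Nuclear oxidative phosphorylation genes fell in 16 of 29 and did not pass in 13 (17 lower adjusted over the list alone). Their median was -0.17 (camera adjusted p = 0.00293, adjusted p = 0.24 with an estimated correlation). Those that fell included COX6C (-0.61 ± 0.079) and NDUFA4 (-0.37 ± 0.055). Hypoxia response genes were lower, with 8 of 19 lower, 2 higher and 9 not past the threshold (13 lower and 2 higher adjusted over the list alone). Their median was -0.25 (camera adjusted p = 0.00458, adjusted p = 0.325 with an estimated correlation). NDRG1 fell from 9.13 ± 0.999 to 1.84 ± 0.229 FPKM (-1.84 ± 0.1), P4HA2, a collagen prolyl hydroxylase, from 20.1 ± 0.0781 to 10.1 ± 1.30 and DDIT4, an inhibitor of mTOR, from 38.3 ± 2.84 to 22.5 ± 1.16. Glycolysis genes were not called (7 higher, 10 lower and 5 not past of 22, and 8 higher and 10 lower adjusted over the list alone, camera adjusted p = 0.875), with HK1 lower (-0.72 ± 0.044) and GAPDH higher (0.33 ± 0.034).

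Cholesterol synthesis genes were higher, with 11 of 24 higher, 1 lower and 12 not past the threshold. Their median was 0.14 (camera adjusted p = 0.0329, adjusted p = 0.418 with an estimated correlation). INSIG1, which retains the SREBP complex in the endoplasmic reticulum, rose from 67.1 ± 0.261 to 133 ± 5.11 FPKM (0.98 ± 0.042), and the synthesis enzymes FDFT1 and IDI1 rose by 0.37 ± 0.042 and 0.52 ± 0.063. That call was lost without LoVo replicate 1 (camera adjusted p = 0.0509), without LoVo-HM replicate 2 (0.0704) and with quantile normalization (0.0674). Fatty acid synthesis and storage genes were not called (8 higher, 6 lower and 5 not past of 19, camera adjusted p = 0.211), although the desaturase SCD rose from 44.1 ± 2.5 to 101 ± 5.24 FPKM (1.18 ± 0.058). Cytosolic ribosomal protein genes were higher by a small amount, with 10 of 26 higher, 1 lower and 15 not past the threshold. Their median was 0.1 (camera adjusted p = 0.0297, adjusted p = 0.708 with an estimated correlation). RPL7A rose (0.19 ± 0.033) and RPL4 fell (-0.16 ± 0.031). The ribosomal call was lost without LoVo replicate 3 (camera adjusted p = 0.138), LoVo-HM replicate 1 (0.0587) or LoVo-HM replicate 2 (0.074), and its median turned to -0.029 with quantile normalization. Ribosomal protein genes, GAPDH, ANXA2 and the ferritin gene FTH1 have many processed pseudogenes, so their single values are uncertain.

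Several other lists held large changes of both signs and were not called. Of 15 drug transport and detoxification genes, 4 rose, 5 fell and 6 did not pass (camera adjusted p = 0.814). The efflux pump ABCG2 rose from 5.74 ± 0.568 to 59.6 ± 1.6 FPKM (3.17 ± 0.070, limma adjusted p = 5.48e-09) and the efflux pump ABCB1 from 1.39 ± 0.0611 to 7.40 ± 0.668 FPKM (1.81 ± 0.087). ABCC1 (-1.26 ± 0.051) and ALDH3A1 (-2.96 ± 0.116) fell. Of 25 glutathione and oxidative stress genes, 10 rose, 11 fell and 4 did not pass (11 higher and 11 lower adjusted over the list alone, camera adjusted p = 0.873). FTH1 rose from 688 ± 20.3 to 1981 ± 66.4 FPKM, and the glutathione peroxidase GPX2 fell from 11.3 ± 0.795 to 0.354 ± 0.0536 FPKM. Of 16 YAP/TAZ targets, 9 rose, 6 fell and 1 did not pass (10 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.331). CYR61 rose (2.02 ± 0.066), and the tissue factor gene F3 fell (-2.27 ± 0.070). Of 23 integrated and unfolded stress response genes, 4 rose, 10 fell and 9 did not pass (camera adjusted p = 0.0818). The amino acid transporter SLC7A5 fell from 252.0 ± 7.66 to 94.2 ± 3.99 FPKM. Of 19 TGF-beta and BMP targets, 5 rose, 7 fell and 7 did not pass (9 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.92). BAMBI, a decoy receptor of the pathway, rose (1.75 ± 0.055), and the transcription factor JUNB fell (-1.34 ± 0.081).

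Of 21 MAPK output genes, 8 rose, 5 fell and 8 did not pass (camera adjusted p = 0.512). The transcription factor ETV1 rose (2.08 ± 0.098), and IER3 fell (-1.76 ± 0.048). Of 22 targets of p53, 10 rose, 7 fell and 5 did not pass (11 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.596). PLK2 rose (0.86 ± 0.042), and PHLDA3 and the cell cycle inhibitor CDKN1A fell (-1.11 ± 0.056 and -0.53 ± 0.053). Of 17 immediate early genes, 5 rose, 5 fell and 7 did not pass (6 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.957). ZFP36, which destabilises cytokine transcripts, fell (-0.69 ± 0.066), and KLF6 rose (0.56 ± 0.067). Of 5 tested neural and neuroendocrine markers, 3 rose and 2 fell (camera adjusted p = 0.814). The neuronal tubulin TUBB3 rose from 27.4 ± 1.85 to 71.7 ± 3.91 FPKM, and SYT1 fell (-1.14 ± 0.093). The median, the mean and camera's direction differed in sign for 6 lists that were not called. These were TGF-beta and BMP targets (median -0.02, mean 0.02, lower), MAPK output (median -0.005, mean 0.08, higher) and glutathione genes (median 0.08, mean -0.06, higher). The others were immediate early genes (median 0.09, mean -0.16, higher), neural markers (median 0.16, mean -0.03, higher) and histones (median 0.05, mean -0.004, higher).

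**Figure D3:**
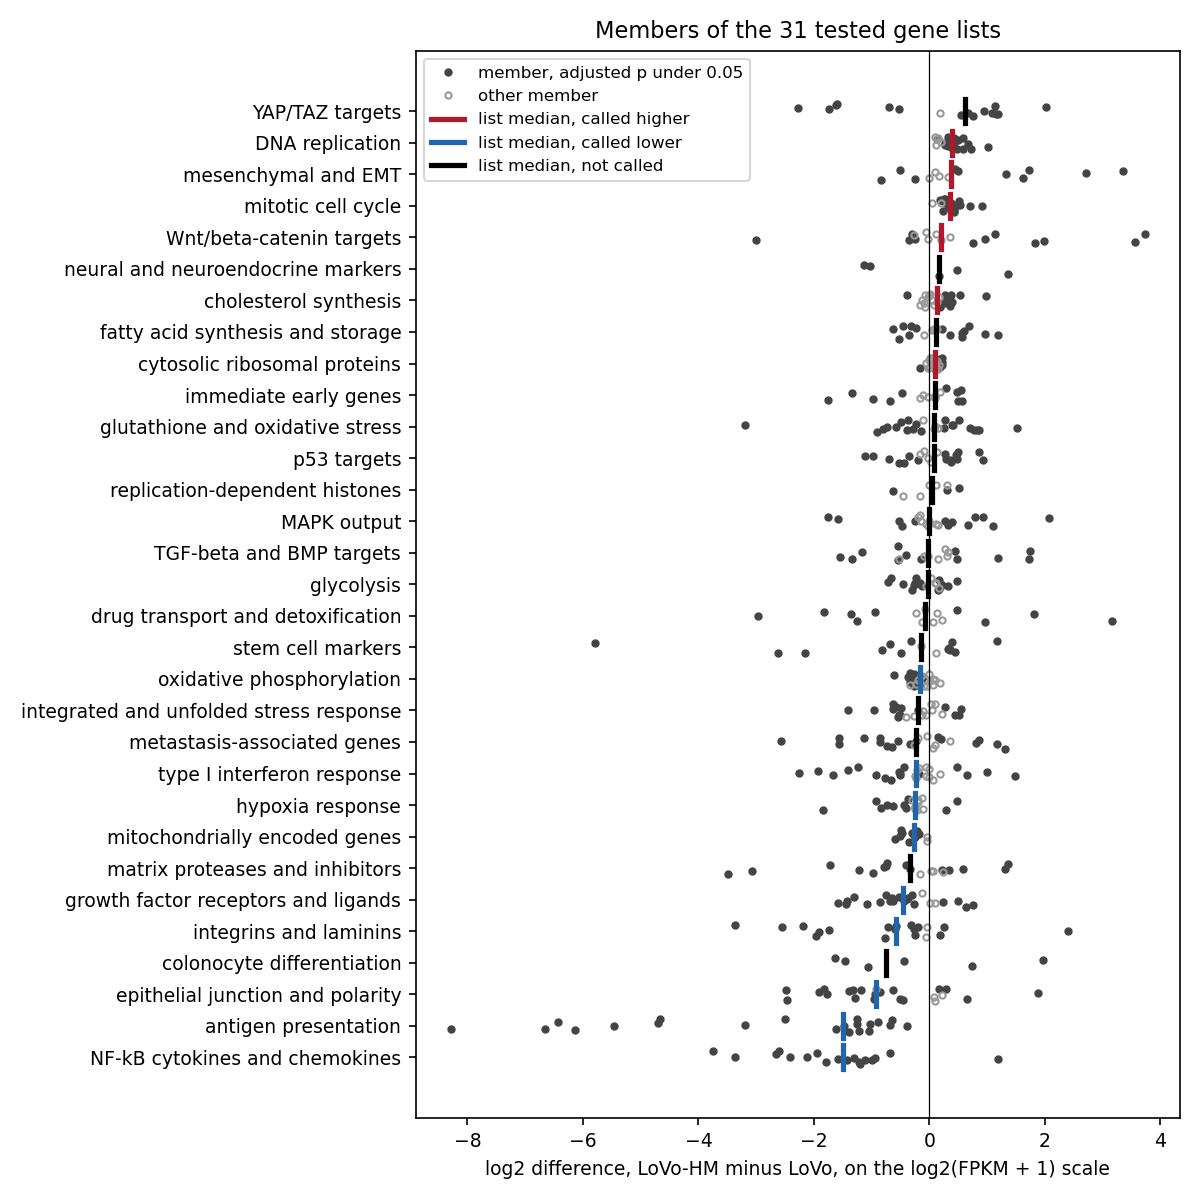
Log2 difference (LoVo-HM minus LoVo, log2(FPKM + 1) scale) of each tested member of the 31 tested gene lists, 1 row per list, where filled points passed limma's adjusted threshold of 0.05, open points did not, and each bar is the list median, red or blue where camera with a preset correlation called the list and black elsewhere. The NF-kB and antigen presentation lists have the lowest medians, -1.5 and -1.49, and DNA replication has the highest median among the called lists, 0.39.

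Markers of other cell types were mostly under the limit for testing. Fibroblast markers had 3 tested members, with COL3A1 higher, ACTA2 lower (-0.86 ± 0.144) and COL1A1 not past the threshold (5.62 ± 0.801 FPKM in LoVo, 4.75 ± 0.436 in LoVo-HM). Of the immune markers 1 of 16 was tested, the lysosomal gene CD68, which fell (-0.32 ± 0.086). The endothelial marker ESAM and the hepatocyte marker CPS1 were the tested members of their lists, at 3.47 ± 0.657 and 3.03 ± 0.485 FPKM in LoVo and 3.16 ± 0.239 and 2.85 ± 0.339 in LoVo-HM, and neither passed the test (limma adjusted p = 0.526 and 0.681). Lung epithelial markers had 4 tested members, of which LAMP3 (-1.54 ± 0.082) and NKX2-1 (-0.74 ± 0.089) fell, AGER rose (0.54 ± 0.142) and NAPSA did not pass.

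No chromosome was called as shifted as a set. Camera's allowance for a preset correlation grows with the size of the set, so a small shift of a whole chromosome could be missed. Median log2 differences ran from -0.054 on chromosome 4 to 0.083 on chromosome 19, and camera called 0 of the 23 chromosomes (1 to 22 and X) after adjustment. At an unadjusted p under 0.05 limma's camera listed 2, chromosomes 17 and 19 (adjusted p = 0.377 for both), and with an estimated correlation it called 0. Chromosome 17 had 226 genes higher and 131 lower, and chromosome 19 had 243 higher and 140 lower. The balance went the other way on others, such as chromosomes 4 (90 higher, 134 lower) and 14 (63 higher, 103 lower).

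Of the 31 tested lists, camera with a preset correlation called 15, 6 higher and 9 lower, of which antigen presentation and the NF-kB list held with an estimated correlation. For the epithelial, integrin, growth factor and mesenchymal lists the estimated correlation lay below the preset 0.01 (-0.02, -0.026, -0.032 and -0.0062). A larger correlation therefore does not account for the loss of these calls. With an estimated correlation, camera takes its p-values from the residual degrees of freedom of the 6 libraries. With a preset correlation it takes them from the number of genes, which gives smaller p-values for the same statistic. The NF-kB list also had an estimated correlation below the preset (0.0081), yet its camera adjusted p went from 2.01e-11 to 0.0306. The values with an estimated correlation therefore do not measure correlation alone. Fry, which compares no list with other genes, called 26 lists for a shift on balance and 31 for change in either direction. The labels do not say that the replicates are separate cultures, so the p-values measure only the spread between these libraries, and with 3 against 3 libraries an exact test of a single gene cannot give a p under 0.1.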

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

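The fit without models lacking a symbol, the fit without mitochondrially encoded genes and camera on ranks were chosen after the results were seen. Of 2547 values of 142 named genes under the alternatives, 2543 kept their direction and side of the threshold. RPL7A (0.04) and MT-ND4L (-0.01) lost the threshold with quantile normalization, and the small differences of RPLP0 (-0.01, quantile) and MYC (0.02, rescaled totals) reversed. A pseudocount of 0.1 gave 1528 genes changed at least 2-fold, 548 higher and 980 lower, because a smaller pseudocount shrinks low genes less. This count, 950 in the main fit, was 1207 with a pseudocount of 0.5 and 1245 with totals rescaled to 1e+06. It was 1344 without mitochondrially encoded genes, a fit that was also rescaled, and 710 with a filter at a mean of 2 FPKM. The deposited totals were 424624 to 439082 FPKM, so rescaling raised all values and gave the pseudocount of 1 less weight. The counts of 1245 and 1344 therefore do not show the effect of equal totals or of removing mitochondrially encoded genes alone. With 1 library left out, 5483 to 5983 genes changed, 2565 to 2861 higher and 2915 to 3122 lower. At least 2-fold, 948 to 977 did, 340 to 350 higher and 601 to 627 lower, with 12 to 15 lists and 0 to 0 chromosomes called. Genes that rose were 48.6% of the changed genes, and 44% without mitochondrially encoded genes to 55.2% with quantile normalization, where 14 of 6508 calls reversed. Camera with an estimated correlation called 2 lists. Apart from that setting, 10 of the 15 called lists held in all 19 alternatives. Lost in at least 1 were the Wnt targets (no filter adjusted p = 0.239, mean of 2 FPKM 0.0666, quantile 0.0861, ranks 0.201, LoVo-HM replicate 2 out 0.0588), interferon (mean of 2 FPKM 0.0866, without mitochondrial genes 0.0502, and with 1 library out), cholesterol (quantile 0.0674, and with 1 library out), mitochondrially encoded (quantile 0.0607) and ribosomal genes. List medians reversed for ribosomal genes (-0.029) and glutathione (0.044, by camera's direction) with quantile normalization, for the Wnt targets (-0.002), matrix proteases (0.005), TGF-beta targets (0.021), neural markers (-0.005) and histones (-0.011) without a filter, for histones without LoVo-HM replicate 3 (-0.021, range with 1 library out to 0.162), and for camera's direction of immediate early genes without LoVo replicate 3 (0.061) or LoVo-HM replicate 2 (0.05, range 0.013 to 0.099). Medians of MAPK output, glycolysis, TGF-beta targets and histones, all near 0, changed sign in other settings too. The cause was not tested. The replicate numbers did not pair the libraries (correlations of same-numbered deviations -0.007, 0.022 and 0.026). With a replicate block 6459 genes changed, 6132 of them among the 6508, 950 at least 2-fold, and 14 lists were called, the Wnt targets being lost (adjusted p = 0.0562). Depth is unknown, so its effect on low values was not assessed.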

Other observations

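The counts over other splits of the libraries were planned, and the other tests in this part were chosen after the results were seen, as were the genes named here. Neighbouring genes of some small clusters moved together between LoVo and LoVo-HM, and the clusters given here were picked for that. The inflammatory caspase genes CASP1 and CASP4 on chromosome 11 fell from 5.53 ± 0.494 to 0.229 ± 0.0941 FPKM (n = 3 per group) and from 11 ± 0.405 to 4.74 ± 0.934, and their neighbour CARD16 from 5.96 ± 0.715 to 0.685 ± 0.228. On chromosome 4 (70196496 to 70251428), CSN3 and its neighbours ODAM and FDCSP were at 17.6 ± 2.77, 8.49 ± 1.11 and 8.11 ± 0.588 FPKM in LoVo-HM, with CSN3 and FDCSP listed at 0 and ODAM at 0.0832 ± 0.110 in LoVo. The placental alkaline phosphatase gene ALPP and its paralog ALPG, which share reads, rose from 0.760 ± 0.115 to 25.6 ± 1.53 FPKM and from 0.132 ± 0.134 to 6.54 ± 0.111. The glutamate transporter SLC1A3 rose from 5.02 ± 0.251 to 59.7 ± 3.06 FPKM.

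Of 28 tested keratins 22 rose and 4 fell in LoVo-HM, those named elsewhere included. On chromosome 17, 13 of 15 rose and 0 fell, and on chromosome 12, 9 of 13 rose and 4 fell (KRT4, KRT6A, KRT6B and KRT6C). KRT5, a basal keratin, rose from 39.9 ± 1.32 to 395 ± 10.7 FPKM, next to the KRT6 genes that fell.

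The fall in transcripts of antigen presentation genes has 3 technical explanations that the tables argue against. A lower copy number of the region would take the neighbouring genes down too, but the 100 other tested genes of the region had a median log2 difference of 0.13 (bootstrap 0.05 to 0.2), and all 5 list members on other chromosomes fell. Reads shared between class II paralogs would leave genes without a close copy in place, but CD74, which has none, fell by a log2 difference of -6.14, and CIITA fell too (-3.2). Immune cells among the LoVo cells would bring their other transcripts, but the highest of 8 such transcripts reached 0.036% of CD74 in any LoVo library. A regulatory change in the subline, with CIITA lower, may underlie the pattern. This is a hypothesis that came from these libraries and that no test here addressed, restoring CIITA in LoVo-HM would test it, and LoVo-HM cells of another origin stay open.

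The keratin pattern was weighed against 2 technical explanations. If reads only moved between paralogs, the summed level of the chromosome 17 keratins other than KRT19 would hold, but it was 21.52 times as high in LoVo-HM. If the cluster had gained a copy, its neighbours would be higher, but 47 other tested genes between 39818117 and 42624842 on chromosome 17 had a median log2 difference of 0.05 (bootstrap -0.1 to 0.18). A change in the regulation of this cluster could account for the rise of the chromosome 17 keratins, as a hypothesis that was not tested. Chromatin accessibility of the cluster in both lines would address that hypothesis. It does not cover the chromosome 12 keratins, of which 9 of 13 rose and 4 fell, and LoVo-HM cells of another origin stay open.

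Few colonocyte markers were expressed in either group. All 25 markers have a row in the table, which argues against their removal by the authors' processing. Of these, 24% had a mean of at least 0.5 FPKM, against 13% of the secretory lineage markers, which is a gut lineage, 6.2 to 35.7% for 6 lists of markers of other tissues and 63.2% of protein-coding genes, while genes of the distal gut were present, HOXA13 at 17.8 ± 0.922 and HOXB13 at 7.88 ± 0.196 FPKM in LoVo. Some genes of basal and stratified epithelia were present in LoVo as well, KRT5 at 39.9 ± 1.32, KRT6A at 151 ± 3.83 and TP63 at 36.1 ± 1.71 FPKM. These genes were picked after their values were seen, and no list of such genes was tested. Other keratins of such epithelia were low in LoVo, with means of 0.276 (KRT14), 0.0418 (KRT15), 0.126 (KRT13), 0.7535 (KRT16) and 1.12 FPKM (KRT17). KRT4, KRT6C and KRT6B had LoVo means of 10.97, 4.63 and 2.25 FPKM. A poorly differentiated colorectal line and cells of another origin cannot be told apart, because no reference profile of LoVo was used here.

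Genes changed at least 2-fold may lie beside each other more often than chance places them. Without pairs of the same family, overlapping pairs and the MHC region, 66 of 9961 neighbouring pairs changed at least 2-fold in the same direction, against a mean of 18.7 (11 to 27) in 10000 shuffles within expression deciles (permutation p = 1e-04, the smallest they can give). The count restates what was seen and tests no cause, so shared regulation and small copy changes both stay open.

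The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 6508 changed genes, 950 changed at least 2-fold, 15 lists and 0 chromosomes, and the highest of the other splits gave 0, 0, 8 and 5. The real result was matched by 1 split, itself, for genes and lists, and by all 10 for chromosomes. Each other split sets 2 libraries of a line and 1 of the other against the rest, so it still holds part of the difference between the lines, and its 5 to 8 lists do not show what camera calls without a difference.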
